A study of Gossypium hirsutum with 12 samples.

How the data were processed

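RNA from cotton flower buds (Gossypium hirsutum, variety BRS 372) was sequenced after infestation by the boll weevil, Anthonomus grandis, a beetle whose larvae feed inside cotton buds. Per the labels' protocols, buds of about 6 mm on plants 3 months old were drilled, a weevil egg close to hatching was placed inside, and the hole was sealed with vaseline. Control buds were drilled and sealed without an egg, so the comparisons set aside the effect of the wound made by drilling. Eggs hatched after about 2 h, per the labels. The labels describe 12 libraries in 4 groups of 3 biological replicates: control and infested buds at 2 h and at 12 h. Each replicate pooled 5 buds from different plants. The libraries were stranded, depleted of ribosomal RNA and read from both ends at 150 bases. The series design also names 48 h; libraries of that time were not described in the labels used here, and their number and controls are not given in the sources used here.

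The submitters' processing notes name Trimmomatic, TopHat2, Cufflinks 2.2.1 and Cuffdiff. The genome build and gene annotation are not given in the sources used here, and coordinates are those of the deposited tables with the start counted from 1. The deposited data were 3 gene tables, 1 per time, each comparing infested with control buds. In these tables the authors gave 1 FPKM value per condition (fragments scaled to transcript length and library size) over its replicates, per the file headers. The authors' log2 fold change is infested over control, and it is infinite where 1 of the conditions is listed at 0. The deposited test statistic, a score signed as the fold, was taken here as the log2 fold change over its standard error, so that an implied standard error is the fold divided by the score. At 48 h, 104 loci had a fold and a score of opposite sign; they were given no implied standard error, and 0 of them were called. The authors' p-values had a floor of 5e-05, and the deposited q-values were used at 0.05 as the authors' own calls. The tables hold no counts, library sizes or values per library, so depth is unknown, no spread between replicates could be computed, and no interval that needs depth is given. The 48 h table holds 2 FPKM columns that match no group of the labels, and these were not used. The 48 h calls, folds, scores and p-values were used as the authors' own comparison.

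The tables differ in what they list. The 2 h table has 188331 loci, of which 110898 carry no annotated gene. The 48 h table has 108421 loci, of which 43961 are unannotated, and the 70373 loci of the 12 h table are all annotated. Among 2 h loci, 4396 exceeded 100000 FPKM; their median length was 23 bases and 6 were called, so FPKM of such short loci was not interpreted. Comparisons between times used genes with 1 tested locus in both tables.

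The calls at each time are the authors' and were not refitted. Computed here were the counts of calls by direction, annotation, chromosome and subgenome, the overlap of calls between times and the clustering of calls along chromosomes. Overlaps were set against the number for independent lists by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 12 tests. They were also set against 10000 permutations within 10 equal classes of mean FPKM at the earlier time of the pair. Clustering was tested with windows of 20 consecutive tested genes and 1000 permutations of the calls. Differences between folds at separate times were tested gene by gene from the implied standard errors, 2-sided with a normal distribution and Benjamini-Hochberg adjustment at 0.05. That test was tested on simulated data with 200 genes differing by 2 on the log2 scale. It recovered 39% of them for 2 h and 12 h (45136 genes), 41% for 2 h and 48 h (39251 genes) and 40% for 12 h and 48 h (41777 genes). Unchanged genes made up 6.02%, 8.89% and 2.44% of its calls in that order. The simulated folds were drawn with each gene's implied standard error, the same error the test used. These shares therefore hold only as far as those errors are right, which the simulation cannot show. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

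The design, the alternatives, 29 gene lists and a rule for named genes were fixed before the data were examined. The files do not pair gene identifiers with names or functions, and 0 of 70478 identifiers matched the reference table of gene names used here (assembly Gossypium_hirsutum_v2.1). None of the 29 lists (hormone pathways, defence proteins, transcription factor families, cell wall, photosynthesis, floral tissue markers and library makeup among them) could therefore be matched, and no list was tested. The rule named the genes of largest change with a functional description, called members of the lists, and up to 8 genes called at all times by their smallest absolute fold. Only its last part could be applied, and it was limited to 2 genes that rose and 2 that fell. Alternatives were a q-value of at most 0.01, a log2 fold of at least 1, FPKM of at least 1, infinite folds left out and q-values recomputed from the p-values. Added after seeing the data were calls from the test statistic, annotated loci only, the longest tested locus of each gene, and the expectation within those classes of FPKM.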

Results

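Transcript levels were compared between cotton flower buds carrying a boll weevil egg or young larva and buds that had been drilled and sealed without one. The labels give 3 pools of 5 buds for each of 4 groups, control and infested at 2 h and at 12 h, and the authors' deposited table for 48 h adds a later comparison. Around the earliest time the egg hatches, and by the later times a larva is inside the bud. Values are the authors' FPKM per condition, so errors given below are standard errors implied by their test statistic, and depth is unknown. The question was how the bud transcriptome changes over the course of infestation.

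At 2 h, infested buds had more loci above control than below it, and the changes were modest. The authors' deposited table called 1505 of 82781 tested loci, 821 higher and 684 lower (54.6% higher). Called loci with a finite fold had a median log2 fold of 0.93 when higher and −0.87 when lower, with a median implied standard error of 0.34. Changes of at least 2-fold, infinite folds included, were seen for 384 higher and 267 lower loci. Among the higher loci 72 were listed at 0 in control buds, and among the lower loci 47 were listed at 0 in infested buds. Annotated genes made up 1231 of the calls (655 higher, 576 lower), and newly assembled loci without a gene made up 274 (166 higher, 108 lower). The share called was 2.28% of tested annotated loci and 0.952% of unannotated ones (2-sided Fisher's exact test, p = 1.7e-46). A called unannotated locus was more than 5 kb from any annotated gene in 187 of 274 cases, against 17763 of 28505 unannotated loci not called. With calls taken from the test statistic instead, 1276 loci passed, of which 200 were among the authors' calls, and the share higher was 45.1%. Of those 1276 loci 225 were annotated and 146 exceeded 100000 FPKM, so that share rests mainly on unannotated loci.

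At 12 h the calls were nearly balanced, with somewhat more genes below control than above it. The authors' deposited table called 1698 of 52123 tested genes, 806 higher and 892 lower (47.5% higher). Among called genes with a finite fold, median log2 folds were 0.99 for higher and −0.91 for lower genes, with a median implied standard error of 0.37. At least 2-fold changes, infinite folds included, numbered 408 higher and 383 lower. Control buds were listed at 0 for 31 of the higher genes and infested buds for 43 of the lower. The balance was not stable, since 51.2% were higher at a q-value of at most 0.01 and 59.3% of the 273 genes called from the test statistic, of which 177 were among the authors' calls.

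At 48 h the calls were more numerous, had larger folds and were mostly upward. Over the 38686 genes tested at all times, 2.49% were called at 2 h, 3.05% at 12 h and 8.82% at 48 h. The authors' deposited table called 4813 of 67351 tested loci, 3121 higher and 1692 lower (64.8% higher). Among called loci with a finite fold, the median log2 fold was 1.48 for higher and −1.05 for lower loci, with a median implied standard error of 0.37. At least 4-fold changes, infinite folds included, were seen for 1185 higher and 372 lower loci. The numbers were 128 and 82 at 2 h and 117 and 106 at 12 h. Infinite folds made up 72 of the 128 and 47 of the 82 at 2 h, and 31 of the 117 and 43 of the 106 at 12 h. Annotated genes accounted for 4211 calls (2803 higher, 1408 lower) and unannotated loci for 602 (318 higher, 284 lower). Control buds were listed at 0 for 255 of the higher loci and infested buds for 135 of the lower. Calls from the test statistic numbered 2899, of which 2303 were among the authors' calls. The number of libraries behind this table and their controls are not given in the sources used here. Time of infestation could therefore not be told apart from these as the source of the larger number of calls.

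**Figure D1:**
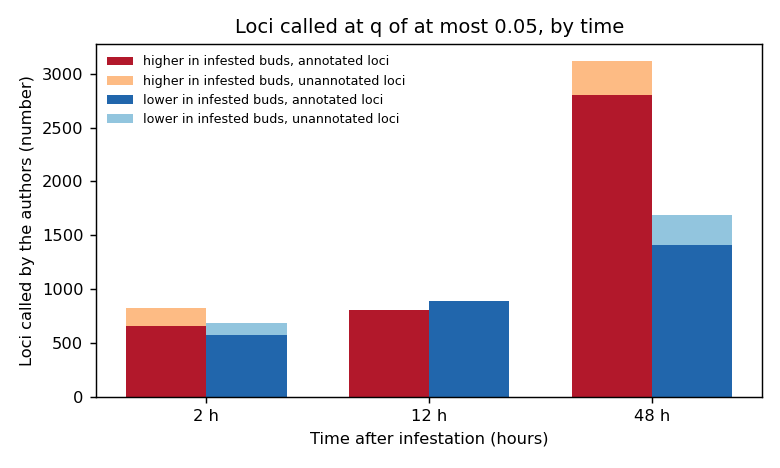
Loci called by the authors at a q-value of at most 0.05 (number, vertical axis) at 2, 12 and 48 h after infestation, with higher loci in red and lower loci in blue and unannotated loci in the paler shade. The 3121 higher loci at 48 h stand against 821 at 2 h and 806 at 12 h.

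The share of genes called did not differ detectably between the A and D subgenomes of this allotetraploid. At 2 h the authors' calls covered 513 of 23338 tested genes on A chromosomes and 596 of 25703 on D chromosomes. The shares were 3.19% and 3.30% at 12 h, and 8.33% and 8.28% at 48 h. No difference passed in 9 Fisher's exact tests over direction and time (smallest adjusted p = 0.618). Of 156 tests of single chromosomes by direction and time, 0 passed after adjustment and 6 had an unadjusted p below 0.05.

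A set of genes kept its direction from 2 h to 48 h. Over the 38686 genes tested at all times, 81 were called higher at every time and 26 lower at every time, where independent lists would give 0.438 and 0.216. A further 20 were called at all times with mixed directions. Gh_D03G1640 (chromosome D03, 46427339 to 46430370) rose at every time, with log2 folds of 2.60 at 2 h, 2.33 at 12 h and 1.99 at 48 h and implied standard errors of 0.34, 0.32 and 0.29. Its FPKM in infested buds was 30.4 at 2 h and 101 at 12 h, which was 6.07-fold and 5.02-fold above control (q = 0.00553 and 0.00341). Gh_D06G1675 (chromosome D06, 55574920 to 55576652) had log2 folds of 2.08, 1.80 and 2.37 with larger implied errors of 0.78, 0.66 and 0.80. Its locus differed between tables, from 55574187 to 55585921 at 2 h and from 55574274 to 55577221 at 48 h, so these folds cover unequal spans. This gene passed the authors' q-values but not calls from the test statistic at any time. Its FPKM was low, 0.687 in control and 2.91 in infested buds at 2 h, and 1.71 and 5.94 at 12 h. Gh_D09G0765 (chromosome D09, 32052760 to 32053545) was lower, at −1.81, −1.97 and −1.93 on the log2 scale, and its FPKM dropped from 14.1 to 4.03 at 2 h and from 8.93 to 2.28 at 12 h. Gh_A08G2381 (scaffold1940_A08, 42550 to 45061) had log2 folds of −2.49, −1.47 and −1.55, and the test statistic gave a call only at 2 h. Its FPKM was low, 1.65 in control and 0.294 in infested buds at 2 h, and 5.88 and 2.13 at 12 h. Positions of the 4 genes are those of the 12 h table, and what they encode is not given in the sources used here.

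**Figure D2:**
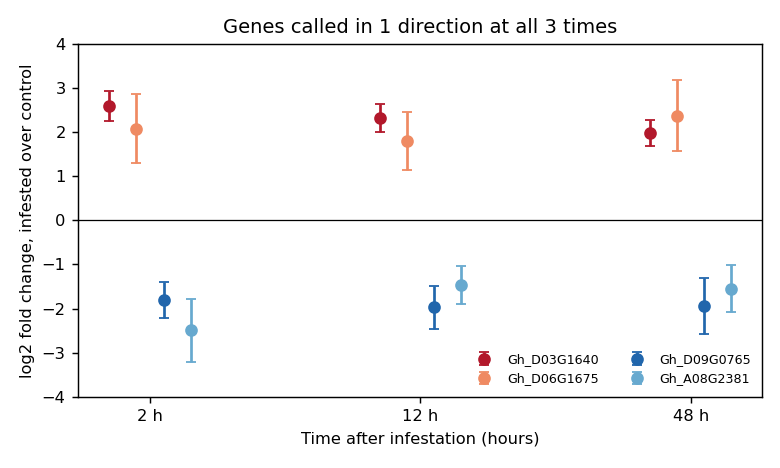
Log2 fold change of infested over control buds (vertical axis) for 4 genes called in 1 direction at 2, 12 and 48 h, with bars of 1 implied standard error. Gh_D03G1640 lies at 2.60, 2.33 and 1.99 and Gh_D09G0765 at −1.81, −1.97 and −1.93.

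Genes called at more than 1 time mostly moved the same way. Between 2 h and 12 h, which have separate control libraries per the labels, 133 genes were higher at both against 8.64 for independent lists (Fisher's exact test, adjusted p = 3.3e-117), and 86 were lower at both against 8.30 (adjusted p = 9.6e-60). Opposite directions, 12 genes higher then lower and 11 lower then higher, did not exceed chance at the authors' threshold. At a q-value of at most 0.01 in both tables, the lower then higher genes did (9 against 2.31; Fisher's exact test, p = 0.000576), as they did with the test statistic (2 against 0.180; Fisher's exact test, p = 0.0141). From 2 h to 48 h, 230 genes were higher at both against 29.1, and 79 were lower at both against 14.0. From 12 h to 48 h, 318 were higher at both against 39.6, and 101 were lower at both against 19.6. The excess of genes lower at both did not pass with calls from the test statistic (2 against 0.773; Fisher's exact test, p = 0.181). The direction was shared by 90.5% of 242 genes called at 2 h and 12 h, by 87.3% of 354 called at 2 h and 48 h, and by 78.8% of 532 called at 12 h and 48 h. Over genes called at either time of a pair, finite folds had Pearson correlations of only 0.32, 0.24 and 0.21 in that order. Among genes tested at all times, most calls were made at 1 time only: 522 of 965 at 2 h, 614 of 1179 at 12 h and 2710 of 3411 at 48 h. At the authors' threshold the 12 h to 48 h pair stood apart because 102 genes were lower at 12 h and higher at 48 h, against 38.5 for independent lists (Fisher's exact test, adjusted p = 4.0e-19). With a q-value of at most 0.01 its ratio of observed to expected was 3.72, against 3.90 for genes lower at 2 h and higher at 12 h. With the test statistic these ratios were 7.90 and 11.1, the latter from 2 genes. Whether the 48 h comparison shares control libraries with the others is not given in the sources used here. The design had planned to look for identical control values, but the 48 h FPKM columns were not used and this was not done. Part of the excess in the same direction with 48 h could therefore come from shared controls.

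**Figure D3:**
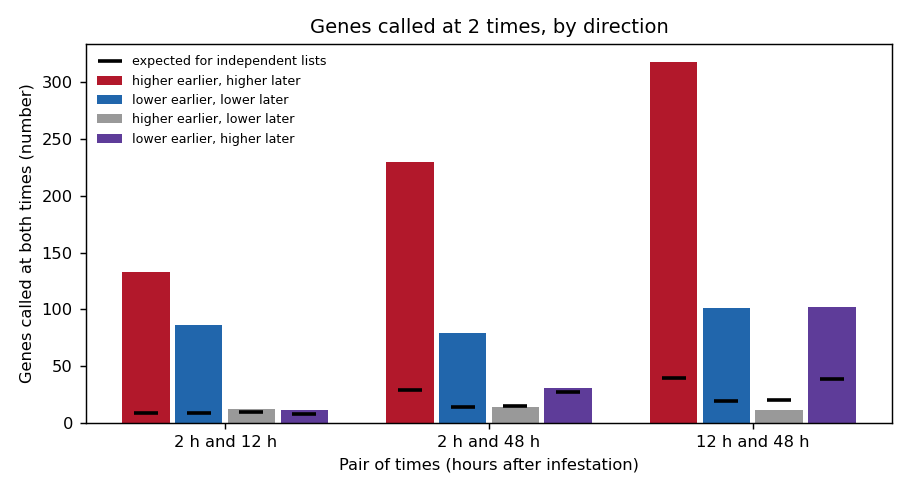
Number of genes called at both of a pair of times (vertical axis) by direction, with black dashes for the number independent lists would share. At 12 h and 48 h, 102 genes were lower then higher where 38.5 were expected.

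Genes called at 2 h in either direction mostly lay on the same side of control later, while genes lower at 12 h went both ways at 48 h. The 502 genes called higher at 2 h had a median log2 fold of 0.17 at 12 h and 0.75 at 48 h, and 60.2% and 80.1% of them were above control at those times. The 463 genes called lower at 2 h had medians of −0.23 at 12 h and −0.34 at 48 h, and 79.1% and 74.1% of them were below control. The 582 genes called higher at 12 h had a median of 0.90 at 48 h. By contrast, the 597 genes called lower at 12 h had a median of −0.29 at 2 h and −0.12 at 48 h. The median at 48 h lay below that of random gene sets (−0.04 to 0.03), and 100 of the 597 were called lower again while 91 were called higher. These make up 32.0% of the 597, against 8.82% called at 48 h among all 38686 genes. The share below control at 48 h was 53.3%, inside the range of random gene sets (46.4% to 54.1%).

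The start of chromosome A13 was the densest stretch of higher genes at 48 h. Between 8016 and 618389, 20 of 37 tested genes were called higher and 0 lower, 35 of the 37 were above control, and the median log2 fold of all 37 was 1.00. No window in 1000 permutations of the calls held as many called genes (13 of 20; p = 0.001, the smallest they can give). The same genes had a median log2 fold of −0.01 at 2 h, with 0 of 35 called, and 0.09 at 12 h, with 1 of 33 called. The next 40 tested genes on A13 had a median of 0.03 at 48 h, and the same span of chromosome D13 had a median of 0.03 over 35 genes. On chromosome A10, between 1448929 and 1656898, 9 of 18 tested genes were lower and 2 higher at 48 h, with a median log2 fold of −1.18 (permutation p = 0.001). The 9 lower genes were short, with a median locus of 453 bases. Short loci of this stretch lay at regular steps, with neighbours starting at 1595039, 1597673, 1600314 and 1602941 at 2 h. The permutations place calls independently, so their p does not allow for neighbouring loci that share reads. Sharing of reads was not tested. In that stretch 0 of 16 genes were called at 2 h and 0 of 16 at 12 h. No stretch passed at 2 h or at 12 h.

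**Figure D4:**
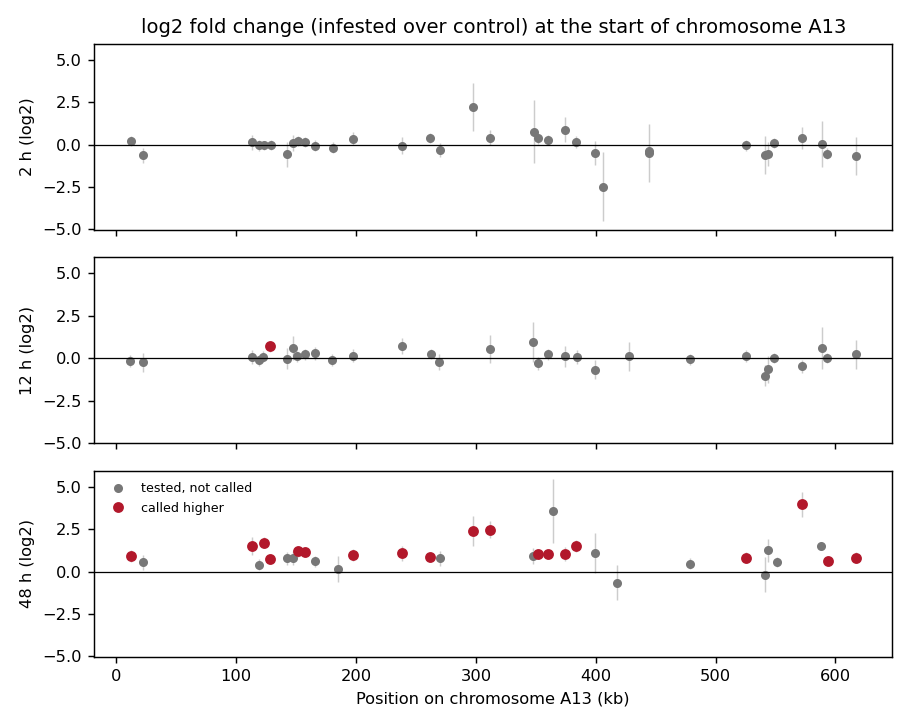
Log2 fold change of infested over control buds (vertical axes) against position on chromosome A13 in kb at 2, 12 and 48 h, with 1 point per tested gene, red where called higher, and bars of 1 implied standard error; genes with an infinite fold are not drawn. At 48 h, 35 of the 37 tested genes were above control, with a median of 1.00 against a median of −0.01 at 2 h.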

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

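The test of folds at separate times was added to the comparisons the design fixed, and the permutation within classes of FPKM and the calls from the test statistic were chosen after seeing the data. The gene by gene test found 34 genes whose fold differed between 2 h and 12 h, 768 between 2 h and 48 h, and 893 between 12 h and 48 h. In the last 2 of these pairs the later fold was the higher one for 625 and 734 genes. These tests rest on implied standard errors and on 1 value per condition.

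The pattern weighed here is the reversal after 12 h, the 102 genes that were lower at 12 h and higher at 48 h. Well measured genes being called more easily in both tables would leave no excess among genes of like abundance. Permutation within 10 equal classes of mean FPKM at 12 h gave 41.4 genes on average and p = 0.0002, the smallest it can give. This argues against abundance at 12 h as the source. Abundance at 48 h was not matched, and FPKM is scaled to length, so the number of reads per gene was not matched either. Loose calls at 12 h would leave no excess among calls from the test statistic, where 21 genes were seen against 2.66, a ratio of 7.90. No biological explanation was tested, and the time of infestation was not separated from the libraries and controls behind the 48 h table, which are not given in the sources used here.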

How the results depend on the processing

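Calls from the test statistic, annotated loci only, the longest locus and the matched expectation were chosen after seeing the data. A q-value of at most 0.01 left 850 loci at 2 h, 913 at 12 h and 3108 at 48 h. A log2 fold of at least 1, infinite folds included, left 651 at 2 h and 791 at 12 h. Both remove calls by construction. Calls from the test statistic numbered 273 genes at 12 h (177 among the authors' calls) and 2899 loci at 48 h (2303 among them). The share higher changed sides at 2 h with the test statistic (45.1%) and at 12 h with a q-value of at most 0.01 (51.2%), a log2 fold of at least 1 (51.6%) and the test statistic (59.3%); the cause was not tested. It moved without changing sides to 58.9% (q-value) and 59.0% (fold) at 2 h, and to 72.0% (q-value), 70.8% (fold), 73.0% (test statistic) and 66.6% (annotated loci) at 48 h. Genes lower at 2 h and higher at 12 h exceeded chance at a q-value of at most 0.01 (ratio 3.90) and with the test statistic (11.1, from 2 genes). Genes higher at 12 h and lower at 48 h, fewer than for independent lists at an unadjusted p of 0.0392, did not pass adjustment (0.0587); their ratio was 0.582 with a log2 fold of at least 1 and 0.747 with the test statistic. Genes lower at both 12 h and 48 h no longer passed with the test statistic (2.59, from 2 genes). With the test statistic, 5 folds of the named genes lost their call. Of the other recomputed values, 136 kept their direction and side of the threshold or stayed within 1.5 times of a count; the 2 h count with the test statistic, 1276, is among them although it shares 200 calls with the authors. No paired analysis was possible because the tables hold no values per library, which also rules out leaving out replicates and other splits of the samples. The gene list alternatives were not run because no list could be matched, and FPKM of at least 1 was not run at 48 h because those columns match no labelled group.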

Other observations

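The tests of chance placement, of a looser shared factor and of noise in the 12 h calls were chosen after the results were seen. Abundant genes leaned upward at 2 h: 62.9% of called genes at 20 FPKM or more were higher, against 48.3% of the rest (Fisher's exact test, p = 8.0e-06). At 12 h the shares were 43.5% and 49.1% (Fisher's exact test, p = 0.0367). Pairs of neighbours within 50 kb were called in the same direction more often than in permuted calls at every time, with 23 against 9.74 at 2 h, 44 against 20.4 at 12 h and 208 against 131 at 48 h (permutation p = 0.001 each, the smallest the permutations can give). Among pairs that overlapped or lay within 1 kb, the numbers were 1 against 1.60 at 2 h, 6 against 2.11 at 12 h and 16 against 19.7 at 48 h (permutation p = 0.796, 0.03 and 0.834). Windows of 20 genes had medians between −0.37 and 0.29 at 2 h and between −0.44 and 0.36 at 12 h, while the extremes at 48 h, 1.06 and −1.16, were the A13 and A10 stretches.

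The A13 stretch was first noticed as 16 of 25 tested genes between 8016 and 384949, and the window scan then set the wider bounds with 20 of 37. Chance placement of calls is argued against by the permutation p of 0.001. Reads running into neighbouring loci are argued against by a median gap of 19.5 kb between called genes. A single factor shared by every gene, such as more copies of the stretch, was set out beforehand as requiring folds equal within their errors. It failed as stated, since Cochran's Q (74.3, n = 35 genes) gave p = 7.8e-05. The largest weight in Q fell on Gh_A13G0057, whose implied error of 0.117 was the smallest of the stretch although its q-value was 0.791. Q was not recomputed without that gene. A looser form was then written because that requirement takes every fold to be equal apart from error: a Q as large was reached by 42.2% of 1132 other runs of 35 genes, so a shared factor added to ordinary variation may remain open, as may joint regulation, which was not tested.

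At 12 h, 1447 of the authors' calls with a test statistic did not pass the adjusted threshold on it. Of all 1698 calls, 1389 had an unadjusted p below 0.05 from the statistic (2-sided, normal distribution). Most of the 1447 therefore missed only the adjusted threshold. Low abundance does not account for the 1447, since 32.9% lay below 5 FPKM (95% exact binomial interval 30.5% to 35.4%). Noise alone is argued against because 78.4% of 1229 such genes had the same sign at 2 h (75.9% to 80.6%), against 59.9% of uncalled genes of like abundance. The share was 75.9% among 191 genes called from the test statistic. Uncalled genes were matched on abundance only, not on size of fold, and the interval takes genes as independent. How the authors' p-values relate to the deposited statistic stays open.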
